A study of Homo sapiens with 12 samples.

How the data were processed

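The 12 libraries of Flp-In T-REx 293 cells, 3 in each of 4 groups, had been made with a stranded mRNA kit and sequenced as 50-nt paired-end reads on a HiSeq2000, per the labels' protocols. Cells were transfected with plasmids for hairpins, either non-targeting or against hnRNP M, and kept in doxycycline. The submitters' processing notes name CASAVA and Cufflinks, with no version or role, and the build hg19. The file headers are those of rMATS tables of skipped exons. The aligner, its settings and the rMATS version are not given in the sources used here.

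The authors deposited 4 tables, one per pairwise comparison, of 35468, 34073, 33263 and 36151 events. Each holds whole-number counts of reads that support inclusion and skipping in each of the 3 libraries of both groups, as the authors deposited them, not normalized. The authors also deposited an inclusion level per library, a fraction of 0 to 1 that is NA where a library had no reads. PSI here is this deposited fraction in percent, in place of a PSI computed from counts and effective lengths as first planned, because effective lengths are not given in the tables used here. Deposited p-values and FDR values per event come from the authors' rMATS test over their own table, and the deposited score of difference is that of the mean inclusion levels.

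Each table names its 2 groups. Which columns belong to which was settled by the counts that 2 tables share: columns of the same group held identical counts for every event in both tables, and columns of different groups for at most 0.055% of events. Reads of HNRNPM were then checked against the labels. The order of the 3 values within a cell carries no replicate number, so libraries are called a, b and c. The number of unused columns of per-sample values is 0. Coordinates are those of hg19 in the files, with 1 added to the start, since 92.46% of exon lengths then matched an annotated exon of the same gene, against 8.96% otherwise. Some 19 gene symbols had been turned into dates by a spreadsheet and were restored from the description beside them. The place of an exon (coding, UTR) was looked up in GENCODE v29 by gene symbol and by the lengths of the exon and its neighbours, with no conversion of coordinates. Symbols of 91.82% of events matched, 75.5% of tested exons were placed as coding or partly coding, and 18.3% had no matched place. No genome sequence of the build was used here.

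Of 48621 events in any table, 19068 were in all 4, with 17310 distinct exons. The event with the most reads was taken for each exon, and 7038 exons were tested that had a mean of at least 20 reads per library and at least 10 reads of each form over all libraries. Reads per library over these exons ranged from 1911320 to 4166455, skipping reads from 105142 to 232291. Reads are not independent molecules, so limits from counts of 0, taken as 3 counts of the total, and the 95% intervals cover counting error only. The lower depth of the Rbfox1 library b (control) and of the knockdown libraries widens the error of PSI there.

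Inclusion and skipping counts of the 12 libraries were fitted per exon by a quasi-binomial model with the 4 groups, in R 4.3.3. Dispersions were moderated over exons with limma 3.58.1 (squeezeVar with a trend on depth) and kept at 1 or more, with a median of 1.05 before and 1.17 after moderation. The prior degrees of freedom were infinite, so every exon received the trend value, and an exon whose own libraries vary more than its depth class is tested too liberally. Likelihood-ratio tests gave the 4 pairwise effects, the difference of the Rbfox1 effect between hnRNP M levels and the 2 average effects. An exon was called with a Benjamini-Hochberg adjusted p under 0.05, a PSI difference of at least 10 points and the same sign in both. Effects are also given as log2 odds ratios with their SE, which are large where a form had no reads. On simulated counts for 7038 exons, of which 200 were changed, changes of 30 points were recovered in 94.0% of cases for Rbfox1 with normal hnRNP M, 77.6% for Rbfox1 after knockdown, 76.1% for knockdown without Rbfox, 70.1% for knockdown with Rbfox1 and 32.8% for the interaction. Changes of 15 points were recovered in 61.2%, 35.8%, 52.2%, 49.3% and 20.9%, in the same order, with 7, 9, 7, 4 and 9 false calls.

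Exons to be named were set by a rule written before the data were examined: for each comparison the 8 largest rises and 8 largest falls among called exons whose groups of 3 did not overlap, 1 per gene, the 2 largest changes in each gene list, 5 per direction for the interaction, 3 per direction class for exons called for both average effects, and members of the Rbfox family and its complex with a mean PSI of 5 to 95%. Some exons that this rule selects are not reported here. How the non-overlap rule applies to the interaction was settled after the data were seen: the groups had to be apart at 1 hnRNP M level at least, in the direction that makes the difference. Gene lists were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 40 tests, and set against 10000 random lists matched on exon number and depth. The 10 lists, also written before, were Rbfox targets in earlier work, the Rbfox family with its complex, RNA processing regulators, actin cytoskeleton and adhesion, microtubules, motors and centrosome, endocytosis and vesicle traffic, chromatin and transcription, kinases, phosphatases and GTPase regulators, epithelial and mesenchymal splice switches, and neuronal microexon genes. Some genes stand in more than 1 list.

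Reads at the events of a gene were also summed for 5221 genes with a mean of at least 50 reads and tested with limma on log2 values scaled for library size with a pseudocount of 0.5. These sums cover exons next to skipped exons only and are a rough measure of expression. On simulated gene totals, with 200 of 5221 genes changed, 67, 66, 65 and 67 of 67 changes by a factor of 2 were recovered in the order of the comparisons above. By a factor of 1.5 these were 52, 57, 51 and 49 of 67, and false calls numbered 11, 16, 9 and 23. The simulated spread between libraries was fixed and not estimated from these data.

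Alternatives were limma on empirical logits (pseudocounts 0.1, 0.5 and 1), dispersions from the 2 groups compared, without the floor or without moderation, no filter or at least 50 mean reads, thresholds of 5 and 20 points, PSI from raw counts, all events, each comparison's own table, the authors' FDR and each library left out in turn. Chosen after the data were seen were each exon's own dispersion where larger, leaving out 2 libraries that stand apart from their groups, and permuting calls within classes of depth and inclusion in control cells. Tables were read and results computed with data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.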

Results

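Skipped-exon splicing was measured by strand-specific mRNA sequencing with 50-nt paired-end reads in Flp-In T-REx 293 cells, a human embryonic kidney line with an integration site for inducible transgenes. The clone used carries a disrupted Rbfox2 reading frame and, per the labels, makes no endogenous Rbfox protein. The comparison covers 4 populations of 3 independently grown cultures each: control cells without Rbfox, control cells with Flag-tagged Rbfox1, and the same pair after knockdown of hnRNP M by hairpins against its 3′ UTR. Rbfox1 binds GCAUG elements and regulates splicing, and hnRNP M is an abundant nuclear RNA-binding protein with which it can associate in a larger complex. The Rbfox1 cells were generated separately, so cell derivation differs along with Rbfox1. The Rbfox1 effect below is the contrast of these cells, which no comparison here separates from their derivation. All cells received doxycycline at 0.5 µg/ml. The measure was the percent spliced in (PSI), the share of transcripts that include an exon, for 7038 exons of 4250 genes. Each library held between 1911320 reads (control with Rbfox1, library b) and 4166455 reads (control with Rbfox1, library a) over these exons, and the median exon was covered by 75 to 164 reads per library. Skipping counts varied between replicates by a chi-square of 1.15 to 4.43 per degree of freedom. The highest values came from library c of the knockdown cells without Rbfox, at 4.26 and 4.43, and from library a of the control cells with Rbfox1, at 3.08 and 3.28. Changes are given in percentage points of PSI, and values as mean ± SD with n = 3 cultures per group unless stated.

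The knockdown was visible in the reads of HNRNPM itself. Reads at its 2 measured exons, scaled for library size as counts per megaread (CPM), stood at 470.0 ± 29.2 CPM in control cells without Rbfox (SD, n = 3) and at 35.1 ± 16.4 CPM after knockdown, 7.47% of control. With Rbfox1 they stood at 493 ± 93.7 and 28.4 ± 0.871 CPM (n = 3 each), 5.76% of control. The labels give a knockdown to 10% of the normal level. All 3 knockdown cultures lay below all 3 controls in both backgrounds, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Rbfox1 moved these reads by less than the spread between replicates, with exact two-sided permutation p values of 0.9 and 1. RBFOX2 reads at 3 exons came to 18.5 ± 1.57, 16.0 ± 2.78, 25.0 ± 2.08 and 19.4 ± 0.787 CPM in the 4 groups, in the order control, control with Rbfox1, knockdown, knockdown with Rbfox1 (n = 3 each). After knockdown they stood at 135% of control without Rbfox and 121% with Rbfox1, with exact two-sided permutation p values of 0.1 and 0.2. With Rbfox1 they stood at 86.6% of the cells without it with normal hnRNP M and at 77.6% after knockdown, with exact two-sided permutation p values of 0.3 and 0.1. The reads show that the gene was transcribed and do not test the disruption of its reading frame. RBFOX1 has no event in these tables and was not analysed here.

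**Figure D1:**
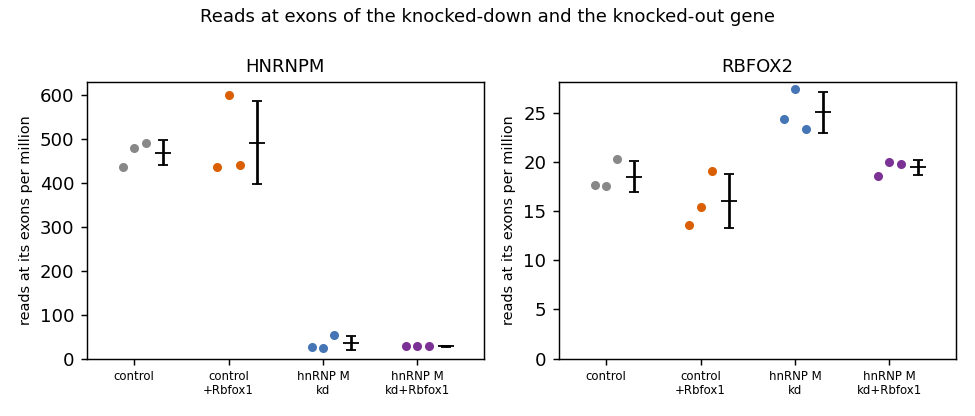
Reads at the exons of HNRNPM (left) and RBFOX2 (right) in CPM, on linear axes from 0, in the 4 groups (kd, knockdown). Points are libraries and bars the mean ± SD of 3; HNRNPM fell from 470.0 to 35.1 CPM without Rbfox and from 493 to 28.4 with Rbfox1.

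The first comparison asked which exons differ between cells with and without Rbfox1 when hnRNP M is present. Several exons were almost completely skipped without Rbfox1 and almost completely included with it. In FN1, which encodes the matrix glycoprotein fibronectin, a coding exon of 273 nt (hg19 chromosome 2, 216257654 to 216257926) rose from 1.00% ± 0.954 to 95.3% ± 2.89. The exon of SYNE2, a nesprin that ties the nucleus to the cytoskeleton, rose from 1.03% ± 1.79 to 97.6% ± 2.57 (coding, 69 nt, chromosome 14, 64682004 to 64682072). In the other direction, an exon of PBRM1, a subunit of a chromatin remodelling complex, fell from 83.5% ± 3.15 to 7.20% ± 2.84 (coding, 156 nt, chromosome 3, 52588740 to 52588895). A 36-nt coding exon of the splicing regulator MBNL1 fell from 96.1% ± 3.44 to 42.4% ± 9.37 (chromosome 3, 152173331 to 152173366).

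Of 7038 exons, 530 in 456 genes were called, 304 with higher and 226 with lower inclusion, and the median absolute change was 23.6 points. FN1 changed by 94.3 points with a log2 odds ratio of 11.03 ± 1.02 (SE) and an adjusted p of 6.22e-84, PBRM1 by -76.3 points with -5.98 ± 0.49 and an adjusted p of 1.22e-58. The largest rise was that of the microtubule-regulating kinase gene MARK3, a 27-nt coding exon on chromosome 14 (103964839 to 103964865), from 0 to 99.4% ± 0.981, and EPB41L2, a membrane skeleton linker, rose from 0 to 99.4% ± 0.557 in a 63-nt coding exon on chromosome 6 (131201284 to 131201346). These starting values rest on 12 and 7 reads, and a count of 0 allows up to 25.0% and 42.9% of reads to be inclusion reads. GOLIM4, a Golgi membrane protein, rose from 1.97% ± 1.72 to 96.4% ± 3.16 and PLEKHG3 from 3.40% ± 1.25 to 100%, with 0 of 147 reads skipping, which allows up to 2.04%. The atypical cadherin gene FAT1 rose from 0 of 147 reads, which allows up to 2.04%, to 92.9% ± 3.55 in a 36-nt exon (chromosome 4, 187511522 to 187511557). In the authors' deposited table the exons of MARK3, EPB41L2, PLEKHG3 and MTSS1L did not pass the FDR. SEPT6, a septin GTPase, fell from 100% (0 of 212 reads skipping, which allows up to 1.42%) to 17.2% ± 7.96 in a 45-nt exon on chromosome X (118759298 to 118759342). STX2, a membrane fusion protein, fell from 85.6% ± 4.41 to 20.9% ± 8.13, TMEM63B from 98.5% ± 2.66 to 37.7% ± 4.44, the calcineurin subunit gene PPP3CB from 95.7% ± 0.361 to 35.7% ± 9.21, and PLD3, in its 5′ UTR, from 96.6% ± 3.98 to 39.0% ± 8.83. MTSS1L fell from 61.1% ± 9.74 to 6.23% ± 10.8 in a 9-nt exon, and its call ended without library c of the control cells with Rbfox1, at an adjusted p of 0.0563. Exons were named for a rise or fall only where the 3 libraries of one group all lay to one side of the other 3. Without the 2 libraries that stand apart the count was 497, and with limma on empirical logits it was 338. It was 279 without moderation and 281 with limma at pseudocount 0.1, and MTSS1L was lost in both.

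**Figure D2:**
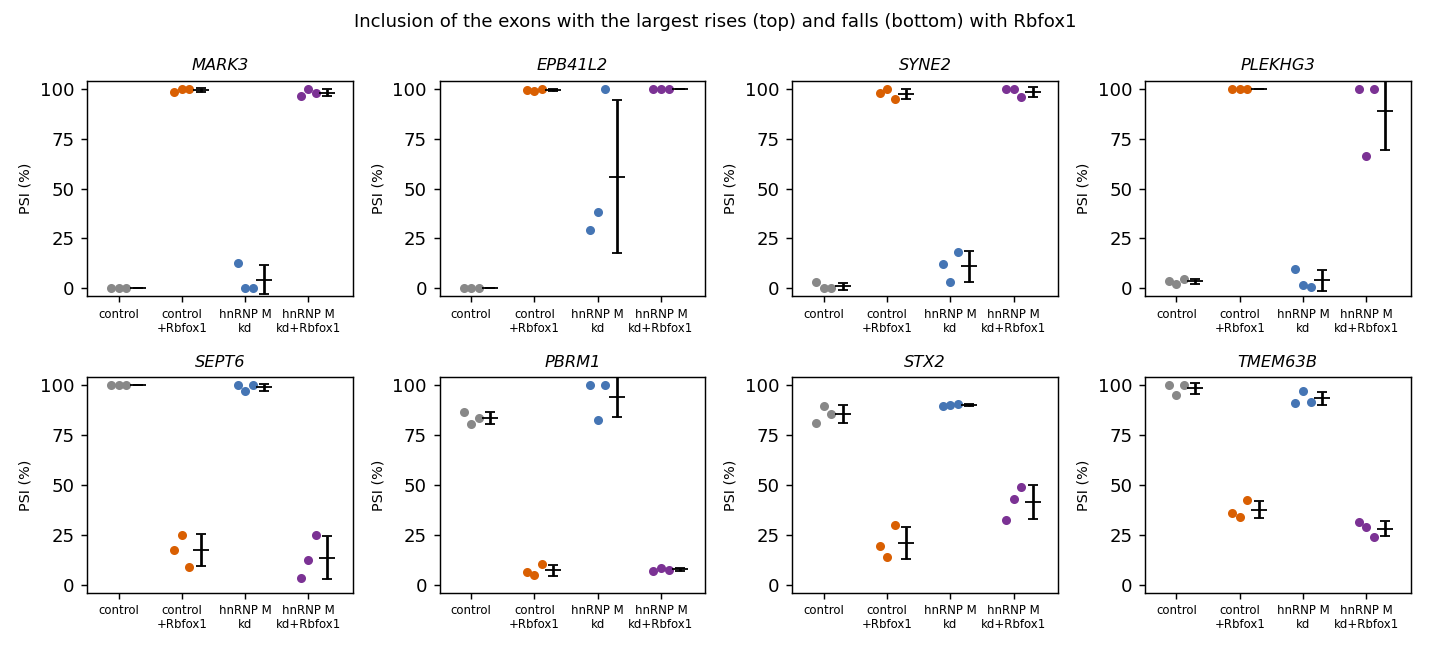
PSI in percent (vertical axes, 0 to 100) of the 4 named exons with the largest rises (top) and the 4 with the largest falls (bottom) on Rbfox1 expression in cells with normal hnRNP M, in the 4 groups (kd, knockdown). Points are libraries and bars the mean ± SD of 3; MARK3 rose from 0 to 99.4% and SEPT6 fell from 100% to 17.2% in control cells, and to 98.2% and 13.6% with Rbfox1 after knockdown.

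After hnRNP M knockdown, the same question was asked of the cells that lacked most of the protein. KIF21A, a kinesin motor, rose from 0 (48 reads, which allows up to 6.25%) to 96.7% ± 5.72 in a 21-nt coding exon (chromosome 12, 39724044 to 39724064), and FN1 from 1.20% ± 0.954 to 92.4% ± 0.379. The 45-nt exon of NF2, the merlin tumour suppressor, rose by 90.1 points from 7.43% ± 3.36 (chromosome 22, 30079009 to 30079053). PBRM1 fell from 94.2% ± 9.99 to 7.67% ± 0.737 and DNM1L, the GTPase of mitochondrial fission, from 74.9% ± 9.5 to 13.6% ± 9.27 in a 33-nt coding exon (chromosome 12, 32891198 to 32891230). AP1B1, a clathrin adaptor subunit, fell from 72.8% ± 6.73 to 12.6% ± 13.9 in a 9-nt coding exon (chromosome 22, 29725701 to 29725709).

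In all, 459 exons of 388 genes were called, 277 with higher and 182 with lower inclusion, with a median absolute change of 25.1 points. Rises of 90 or more points were also seen in MARK3 (93.9 points, adjusted p 7.53e-20), the adhesion receptor gene GPR126 (93.6, 9.46e-65), FAM126A (91.9, 5.79e-40) and the kinase gene MAST4 (96.3, 1.88e-14). Inclusion fell by 85.4 points in SEPT6 (adjusted p 2.77e-23), by 65.4 in TMEM63B (9.10e-24), by 54.9 in PLD3 (7.89e-12), by 53.6 in ESYT2 (1.56e-25) and by 53.1 in MBNL1 (1.90e-21). Of the 27 exons named for this comparison, 0 lost the call in any leave-one-out fit. Without moderation 225 exons were called, with limma at pseudocount 0.1 287, and without the 2 libraries that stand apart 422. The exons of KIF21A, MAST4 and FAM126A did not pass the FDR in the authors' deposited table.

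The Rbfox1 effect had the same direction at both hnRNP M levels for most called exons. ZRANB2, a splicing factor gene, rose by 56.0 points with normal hnRNP M and by 55.0 after knockdown, the spindle protein gene NUMA1 by 76.0 and 73.9, and MBNL1 fell by 53.7 and by 53.1. STX2 went from 85.6% ± 4.41 to 20.9% ± 8.13 with normal hnRNP M and from 90.3% ± 0.551 to 41.4% ± 8.39 after knockdown. MTSS1L went from 61.1% ± 9.74 to 6.23% ± 10.8 and from 47.8% ± 22.5 to 30.2% ± 27.1, the latter not called (adjusted p 0.661). The difference between the levels was not called for STX2 (adjusted p 0.914) or MTSS1L (0.640). Of the 679 exons called at either level, 628 (92.5%) changed in the same direction, and 310 were called at both, all in the same direction, where independent lists would share 34.6. Across the 7038 exons the changes correlated with Pearson's r of 0.749 and Spearman's rho of 0.392, each with a permutation p of 0.0001, the smallest that the 10000 permutations give, and the slope was 0.738. With no filter on low counts r was 0.241, and with PSI from raw counts 0.851. This is a correlation across exons, which are not independent replicates, and the 2 contrasts share no library.

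**Figure D3:**
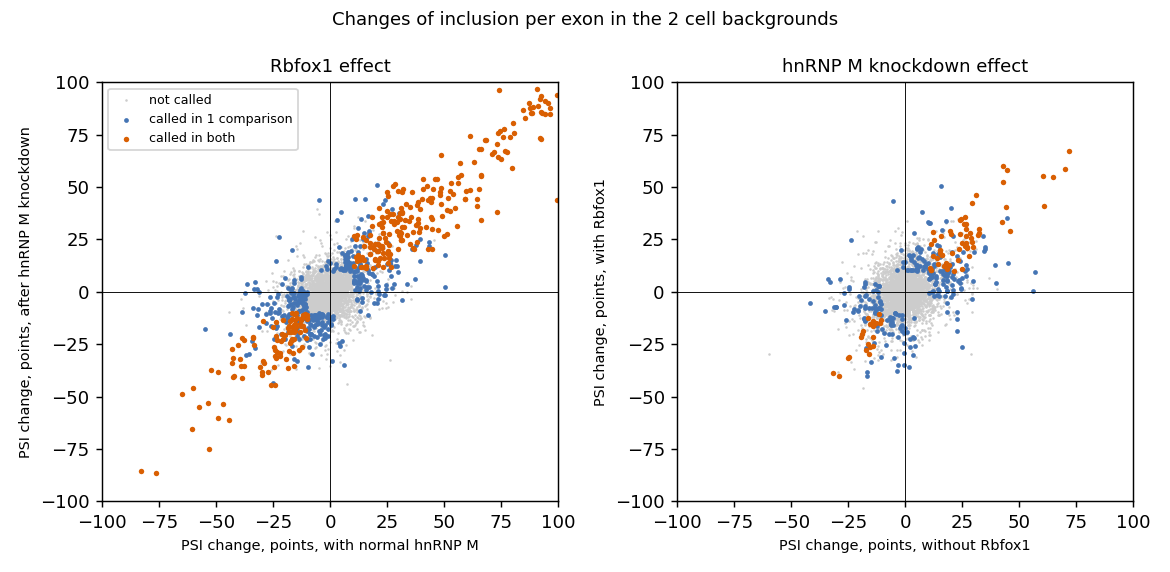
PSI change in percentage points of each of 7038 exons, for the Rbfox1 effect (left; with normal hnRNP M on the horizontal axis, after knockdown on the vertical) and for the knockdown effect (right; without Rbfox1 on the horizontal axis, with Rbfox1 on the vertical). Each point is an exon, colored by whether it was called in neither, 1 or both comparisons; r was 0.749 on the left and 0.403 on the right.

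Knockdown of hnRNP M without Rbfox changed fewer exons. APLP2, an amyloid precursor-like membrane protein, rose from 31.6% ± 3.72 to 92.0% ± 1.80 in a 168-nt coding exon (chromosome 11, 129993507 to 129993674). SYNCRIP, itself an hnRNP, rose from 73.2% ± 2.52 to 99% ± 1.17 (160 nt, chromosome 6, 86351010 to 86351169), and the cytoskeletal crosslinker gene MACF1 from 11.1% ± 3.61 to 40.9% ± 5.35 (coding, 111 nt, chromosome 1, 39946592 to 39946702). FAM48A rose from 7.5% ± 8.65 to 79.3% ± 18.2 (162 nt, chromosome 13, 37628272 to 37628433), and the transcription factor gene PATZ1 from 18.1% ± 5.40 to 88.0% ± 10.4 (coding, 138 nt, chromosome 22, 31724773 to 31724910). A 54-nt coding exon of DLG1, a scaffold of cell junctions, fell from 90.3% ± 5.97 to 61.1% ± 6.29 (chromosome 3, 196876614 to 196876667), and KIAA1191 fell from 68.6% ± 7.11 to 38.2% ± 1.24.

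The test called 223 exons in 201 genes, 144 higher and 79 lower, with a median absolute change of 18.5 points. APLP2 changed by 60.4 points with a log2 odds ratio of 4.59 ± 0.23 (SE) and an adjusted p of 1.09e-133, MACF1 by 29.8 points (2.48 ± 0.16, 1.77e-58), SYNCRIP by 25.8 points (4.97 ± 0.75, 6.06e-29) and DLG1 by -29.3 points (-2.50 ± 0.52, 1.38e-05). Rises were also called for EXOC2 of the exocyst (60.8 points, adjusted p 5.68e-08), ZNF195 (57.0, 2.11e-05), ARHGAP10 (45.9, 4.32e-07), TBC1D15 (32.1, 1.57e-13) and the catenin gene CTNND1 (27.1, 4.00e-07, exon starting at 57558966). Without the 2 libraries that stand apart the count was 179.

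Several of the other named exons of this comparison lost the call when 1 library was left out, with adjusted p then between 0.0514 (FEZ2) and 0.350 (CLK4). EPB41L2 stood at 56.0% ± 38.4 after knockdown, from 2, 5 and 4 reads in libraries a, b and c against 7 reads in the 3 control libraries. It entered the test through the reads of the Rbfox1 cells, and was lost without any control library or knockdown library c, CARD8 (fell by 41.6 points) without control a or b or knockdown b, and INPP1 (by 35.4) without any 1 of the 6. CUTC (fell by 31.7) was lost without knockdown b, and DNM2, the dynamin of endocytosis (by 31.1), without control b or knockdown c. RGL2 (fell by 28.5) and FEZ2 (by 26.8) were lost without control a or b or knockdown a or c. MAP3K7 (rose by 18.5) and OFD1 (by 18.4) were lost without control b or knockdown a or c. The kinase gene CLK4 (rose by 24.3) was lost without control a or c or knockdown a or b. CEP170 (by 26.1) was lost without control b or c or knockdown b or c, EED of Polycomb (by 34.8) without control b or c or knockdown a or c, and MAPK9 (by 28.7) without control b or knockdown b. With limma on empirical logits 37 exons were called, and 15 of the 27 named exons were lost, while FAM48A, PATZ1, APLP2, ZNF195, ARHGAP10, INPP1, DLG1, SYNCRIP, TBC1D15 and MACF1 were among those that passed. The authors' FDR did not call 14 of the 27, ARHGAP10 and the exons lost here without 1 library. Without moderation 23 exons were called and 20 of the 27 lost, with FAM48A, PATZ1, APLP2, KIAA1191, SYNCRIP, TBC1D15 and MACF1 still called. With limma at pseudocount 0.1 PATZ1, KIAA1191 and SYNCRIP were lost, and with PSI from raw counts the rise of SYNCRIP was under 10 points. Only 4 of the 27, FAM48A, APLP2, TBC1D15 and MACF1, were lost under no alternative.

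**Figure D4:**
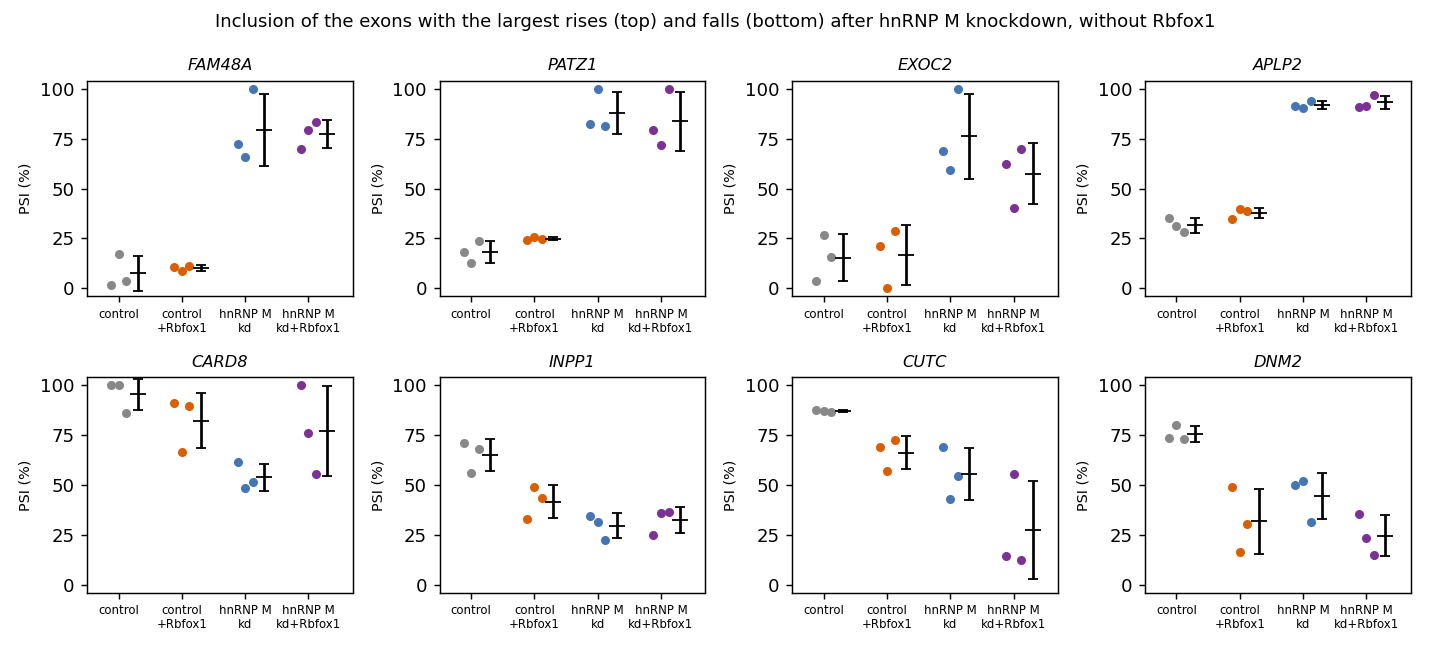
PSI in percent (vertical axes, 0 to 100) of the 4 named exons with the largest rises (top) and the 4 with the largest falls (bottom) after hnRNP M knockdown without Rbfox1, in the 4 groups (kd, knockdown). Points are libraries and bars the mean ± SD of 3; APLP2 rose from 31.6% to 92.0% with little spread, while CUTC fell from 87.1% to 55.5% with an SD of 13 points.

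With Rbfox1 present, hnRNP M knockdown raised APLP2 from 37.8% ± 2.48 to 93.3% ± 3.38, SYNCRIP from 66.3% ± 2.33 to 98.9% ± 1.10 and FAM48A from 10.3% ± 1.40 to 77.4% ± 6.99. NAP1L4, a nucleosome assembly protein, rose from 17.3% ± 4.04 to 75.2% ± 21.3 in a 143-nt exon of its 5′ UTR (chromosome 11, 3010359 to 3010501), and ARHGEF7, an exchange factor for Rac, from 61.0% ± 11.2 to 96.7% ± 2.94 (coding, 131 nt, chromosome 13, 111862219 to 111862349). DLG1 fell from 87.3% ± 3.32 to 47.2% ± 8.62, and MORF4L2, a subunit of histone-modifying complexes, from 77.1% ± 0.777 to 50.7% ± 4.09 (122 nt, chromosome X, 102933427 to 102933548). AGAP3, a GTPase-activating protein gene, fell from 63.6% ± 3.16 to 32.0% ± 3.83 (coding, 138 nt, chromosome 7, 150837066 to 150837203).

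The test called 195 exons in 175 genes, 119 higher and 76 lower, with a median absolute change of 19.5 points. Adjusted p was 7.60e-84 for APLP2 (55.5 points), 1.96e-31 for SYNCRIP (32.6), 1.45e-14 for MORF4L2 (-26.5), 2.41e-12 for NAP1L4 (57.9), 3.70e-07 for ARHGEF7 (35.7) and 1.68e-06 for DLG1 (-40.1). FBXO18 (60 points, 3.17e-06), PATZ1 (58.8, 6.79e-06), ZNF239 (52.2, 0.000713), TMEM56-RWDD3 (46.3, 3.78e-05) and AGAP1 (27.9, 1.45e-05) also rose. Without the 2 libraries that stand apart the count was 168, with limma it was 42, and 18 of the 31 named exons were lost with limma. The authors' FDR did not call 19 of the 31, ZNF239 and TMEM56-RWDD3 among them. Without moderation 18 exons were called and 28 of the 31 lost, all but APLP2, SYNCRIP and MORF4L2. SYNCRIP was lost with limma at pseudocount 0.1 and with PSI from raw counts, which leaves 2 of the 31, APLP2 and MORF4L2, lost under no alternative. Without library c of the knockdown cells with Rbfox1 the count was 132, the lowest of the leave-one-out counts.

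Other named exons of this comparison were again lost when 1 library was left out, with adjusted p then up to 0.603 (TMEM64). Control here means control cells with Rbfox1 and knockdown the knockdown cells with Rbfox1. ARAP1 (fell by 40.0 points) and TMEM64 (by 35) were lost without knockdown b, NAF1 (by 37.7) without knockdown c, and DTX2 (by 38.4) without control a or knockdown a. SLC25A3 (fell by 36.0) was lost without control a or b or knockdown a or c, SLC25A14 (rose by 50.3) without control b or c or knockdown b or c, and NDUFA13 (fell by 35.1) without any 1 of the 6. CUTC (fell by 38.9) was lost in 7 of the 12 leave-one-out fits: without control a or c, knockdown a or c, and also without library b or c of the control or library b of the knockdown cells that lack Rbfox. CTTN, the actin regulator cortactin (rose by 15.8), was lost without control c or knockdown a, ATP5C1, an ATP synthase subunit (by 14.5), without control c or knockdown b, CLK4 (by 34.6) without control c or knockdown b or c, and CTNND1 (by 23.2) without control a or knockdown c. This CTNND1 exon starts at 57558857 and overlaps the different CTNND1 exon named for knockdown without Rbfox. DCTN4 of dynactin (fell by 12.3) was lost without control a or knockdown b or c, EXOC2 (rose by 40.9) without control a or knockdown a or c, and BRD1 (by 20.4) without control a or c or knockdown a or c. EXOC7 (rose by 10.8) was lost without control a or c, any knockdown library, or library a of the knockdown cells that lack Rbfox. ITSN1 (by 29.3) was lost in 9 fits: without control a, any knockdown library, any control library that lacks Rbfox, or library a or b of the knockdown cells that lack it.

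The knockdown effects in the 2 backgrounds shared a direction for most called exons. TBC1D15 stood at 0.467% ± 0.808 and 0.900% ± 1.56 before knockdown and at 32.6% ± 5.91 and 31.1% ± 13.9 after it, without and with Rbfox1, and MACF1 at 36.6% ± 2.27 after knockdown with Rbfox1. Of 337 exons called in either background, 292 (86.6%) changed in the same direction, and 81 were called in both, all in the same direction, where independent lists would share 6.18. Across exons, r was 0.403 and rho 0.263, each with a permutation p of 0.0001, the smallest that 10000 permutations give.

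Whether the Rbfox1 effect depends on hnRNP M was tested as the difference between the 2 Rbfox1 effects. HMGA1, an architectural chromatin protein, went from 54.5% ± 1.55 to 48.0% ± 4.36 on Rbfox1 expression with normal hnRNP M and from 42.9% ± 2.31 to 50.6% ± 3.32 after knockdown, in a 114-nt exon of the 5′ UTR (chromosome 6, 34204981 to 34205094). The noncoding RNA ZNFX1-AS1 went from 20% ± 1.71 to 41.5% ± 9.49 and from 40.1% ± 8.03 to 39.0% ± 0.493 (62 nt, chromosome 20, 47897440 to 47897501). C1orf144 went from 41.0% ± 2.72 to 46.7% ± 3.03 and from 25.0% ± 1.38 to 17.3% ± 1.97 (50 nt, chromosome 1, 16717870 to 16717919). MPI, an enzyme of mannose metabolism, went from 58.0% ± 3.66 to 63.4% ± 8.98 and from 57.4% ± 6.32 to 34.1% ± 3.7 (coding, 128 nt, chromosome 15, 75182868 to 75182995).

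The interaction was called for 15 exons of 13 genes, 6 of them with a more positive and 9 with a more negative Rbfox1 effect after knockdown, and 549 had an unadjusted p under 0.05. In the simulation with 200 changed exons this test recovered 14 of 67, 22 of 67 and 50 of 66 changes of 15, 30 and 60 points. It made 9 false calls among unchanged exons. The simulated set held more calls than the 15 here, so the 9 do not tell how many of the 15 are false. The directions were 1 and 7 without library c of the knockdown cells with Rbfox1, 2 and 6 without its library b, 3 and 8 without library a of the knockdown cells without Rbfox, 5 and 12 with PSI from raw counts, 2 and 5 at 20 points and 0 and 2 with each exon's own dispersion where larger. The differences of the Rbfox1 effect were 14.2 points in HMGA1 (adjusted p 1.44e-07), -22.6 in ZNFX1-AS1 (2.80e-08), -13.5 in C1orf144 (0.000223) and -28.6 in MPI (0.00941). They were 26.1 points in RHBDD2 (0.0144), 21.5 in ISCU (0.0394), 18.5 in MLX (0.0391), 15.5 in PPHLN1 (0.0391), -41.3 in HAPLN3 (0.0261) and -25.5 in TRA2A (0.0254). The calls of 7 of these 10 exons ended when 1 library was left out. This was so for RHBDD2 in 6, ISCU in 8, MLX in 9, PPHLN1 in 10, HAPLN3 in 7, TRA2A in 4 and MPI in 2 of the 12 fits, with adjusted p then from 0.0503 to 0.378. For MPI these were library c of the control cells with Rbfox1 and library a of the knockdown cells without Rbfox, and for TRA2A library a of the control and c of the knockdown cells without Rbfox and library b of the control and c of the knockdown cells with Rbfox1. Writing C and K for control and knockdown cells without Rbfox and CR and KR for those with Rbfox1, RHBDD2 was lost without C b, CR b, CR c, K a, KR b or KR c. ISCU was lost without C b, C c, CR c, K b, K c or any KR library, and HAPLN3 without C a, C c, CR a, K a, K b, KR a or KR b. MLX was lost without C b, C c, CR a, CR b, K a, K b or any KR library, and PPHLN1 without any library but CR c and K b. The count fell to 8 without library b of the control cells with Rbfox1 or library b or c of the knockdown cells with Rbfox1, and to 9 without library a of the control cells without Rbfox. With limma the count was 0, and 0 without moderation of the dispersion.

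The series title names co-regulation by the 2 proteins, and exons called for both average effects were counted. In CTNND1, which encodes the p120 catenin of adherens junctions, an exon of 289 nt (chromosome 11, 57558857 to 57559145) stood at 28.8% ± 1.60 in control cells, 59.2% ± 1.70 with Rbfox1, 55.3% ± 10.3 after knockdown and 82.4% ± 10.4 with both. Both average effects were positive there, 28.8 points for Rbfox1 (adjusted p 3.08e-13) and 24.9 for knockdown (9.10e-08). KIAA1191 moved in opposite directions, from 68.6% ± 7.11 to 97.1% ± 0.902 with Rbfox1, to 38.2% ± 1.24 after knockdown and to 89.7% ± 2.60 with both (87 nt, chromosome 5, 175786484 to 175786570). TNRC18 also moved in opposite directions, from 41.4% ± 5.14 to 67.0% ± 2.91 with Rbfox1, 16.5% ± 6.58 after knockdown and 35.9% ± 11.4 with both (430 nt, chromosome 7, 5460691 to 5461120).

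Of 603 exons called for the average Rbfox1 effect and 282 for the average knockdown effect, 69 were called for both, where independent lists would share 24.2 (Fisher's exact odds ratio 3.77, p 1.90e-16). Both effects had the same direction in 47 (independent lists, 12.4) and opposite directions in 22 (11.8), with 26 rising and 21 falling for both, 8 rising with Rbfox1 and falling with knockdown and 14 the reverse (Fisher's exact p for direction 0.00326). The test of direction does not allow for the starting inclusion of an exon, which limits the direction of both effects alike. When the calls were permuted within classes of depth and mean inclusion, the median number shared was 70 and the highest of 1000 permutations 91. Mean inclusion moves with the change itself, and with classes of depth and inclusion in control cells without Rbfox the median was 58 and the highest 78. Both averages use all 12 libraries: in 20 simulated sets of unchanged groups, 0 exons were called for both and the covariance of the effects averaged 0.308, against 5.81 observed. With no exon changed, these sets show only that the shared libraries add little covariance by themselves. They do not test whether 2 separate effects would share as many exons or directions. EPB41L2 (71.7 and 28.3 points) and CUTC (-24.5 and -35.3) also had the same direction, and EXOC3L1 (-20.1 and 27.2) opposite ones. The knockdown call of EPB41L2, with few reads in the cells without Rbfox, was lost in 9 of the 12 leave-one-out fits (all but those without library c of the control cells with Rbfox1 or library a or b of the knockdown cells without Rbfox), with adjusted p from 0.0613 to 0.117. The Rbfox1 call of CUTC was lost without library a or c of the knockdown cells with Rbfox1 (0.0543 and 0.0854), and that of EXOC3L1 without library a of the knockdown cells without Rbfox or b of those with Rbfox1 (0.0798 and 0.108). Without the 2 libraries that stand apart 67 exons were called for both, with limma 40 and without moderation 22. Without moderation EXOC3L1 lost both calls, CUTC that for Rbfox1 and EPB41L2 that for knockdown. With PSI from raw counts CTNND1 lost the knockdown call.

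The 10 lists of genes were set before the data were examined, and each gene counted as called where at least 1 of its exons was. They were drawn up from general knowledge, which may favour genes already known for alternative exons. The lists share genes, such as FN1 and EPB41L2 in both the Rbfox target and the actin list, so their results are not independent. No list was tested without the Rbfox targets it shares. The random lists were matched on exon number and depth, not on inclusion. Among 30 tested genes named as Rbfox targets in earlier work, 22 were called for Rbfox1 with normal hnRNP M (18 with rises, 2 with falls, 2 with both; adjusted p 8.61e-15) and 21 after knockdown (8.61e-15), KIF21A and FN1 among them. The number of their exons called was 34 adjusted over the list alone and 30 over all exons with normal hnRNP M, and 33 and 29 after knockdown. CLSTN1, a calsyntenin of vesicle transport, rose from 1.17% ± 1.33 to 81.6% ± 12.1 with normal hnRNP M, and PTBP2, a neuronal splicing repressor, from 20.1% ± 23.8 to 91.2% ± 7.79. PTBP2 was not called without moderation or with limma at pseudocount 0.1. Only 3 genes of this list were called for each knockdown effect (adjusted p 0.209 and 0.160).

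Of 66 genes of the actin cytoskeleton and adhesion, 33 and 32 were called for Rbfox1 at the 2 hnRNP M levels (26 and 27 with rises alone; adjusted p 8.61e-15 and 2.50e-15), such as MPRIP, a myosin phosphatase partner, at 7.30% ± 0.529 and 98.5% ± 1.55 without and with Rbfox1. Epithelial and mesenchymal splice switches gave 16 and 15 of 23 (1.93e-10 and 2.80e-10), with ABI1, of an actin-nucleating complex, at 28.9% ± 3.48 and 97.2% ± 1.42 and GIT2 at 18.4% ± 5.99 and 92.2% ± 2.06. Kinases, phosphatases and GTPase regulators gave 32 and 28 of 83 (1.43e-10 and 1.40e-09), endocytosis and vesicle traffic 23 and 21 of 67 (6.86e-07 and 7.89e-07), and neuronal microexon genes 19 and 14 of 46 (3.09e-07 and 9.95e-05), with SLIT2, an axon guidance cue, at 3.50% ± 3.90 and 83.4% ± 3.86. Chromatin and transcription gave 22 and 20 of 82 (9.46e-05 and 9.46e-05), with the transcription factor genes NFYA at 0.467% ± 0.808 and 85.9% ± 12.6 and FOXM1 at 6.30% ± 0.700 and 86.9% ± 3.58. Microtubules, motors and centrosome gave 12 and 11 of 40 (0.00139 and 0.00139), and RNA processing regulators 21 and 18 of 87 (0.000720 and 0.00171). With a minimum of 50 mean reads the microtubule list lost its call with normal hnRNP M, at an adjusted p of 0.0818. Exons called for these lists with normal hnRNP M numbered, adjusted over the list alone and over all, 49 and 44 for actin, 21 and 20 for splice switches, 42 and 39 for kinases, 30 and 28 for endocytosis, 24 and 23 for microexon genes, 30 and 27 for chromatin, 14 and 13 for microtubules and 26 and 25 for RNA processing.

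For knockdown, RNA processing regulators gave 12 of 87 genes without Rbfox (7 with rises, 5 with falls; adjusted p 0.00139) and 10 with Rbfox1 (0.00442), SYNCRIP and CLK4 among them, and kinases and GTPase regulators 12 of 83 (0.00106) and 10 (0.00323). Without Rbfox, neuronal microexon genes gave 8 of 46 (0.00219), chromatin and transcription 11 of 82 (0.00255) and splice switches 5 of 23 (0.00580), and with Rbfox1, endocytosis and vesicle traffic gave 11 of 67 (0.000193). Chromatin and splice switches lay at percentiles 96.9 and 97.0 of random lists of like exon number and depth, inside the central range, while the other 24 of the 26 calls lay outside it. All 8 knockdown calls were lost with limma at some pseudocount and without moderation. With a pseudocount of 0.5, limma gave an adjusted p of 0.656 for RNA processing, kinases and chromatin, 1 for splice switches and 0.471 for microexon genes without Rbfox, and 0.0760 for RNA processing and 0.279 for kinases with Rbfox1. For endocytosis with Rbfox1 the adjusted p was 0.346 without moderation and 0.0725 with each exon's own dispersion. For kinases without Rbfox it was 0.0562 with PSI from raw counts. The splice switches were also lost without library b of the control cells without Rbfox (adjusted p 0.279), and kinases with Rbfox1 without library c of the knockdown cells with Rbfox1 (0.113). The remaining knockdown tests gave, without and with Rbfox1, 7 and 6 of 66 for actin (0.0517 and 0.0704), 2 and 1 of 40 for microtubules (0.793 and 1), 7 of 67 for endocytosis without Rbfox (0.0535), and with Rbfox1 4 of 82 for chromatin (0.663), 2 of 23 for splice switches (0.296) and 5 of 46 for microexon genes (0.0540).

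**Figure D5:**
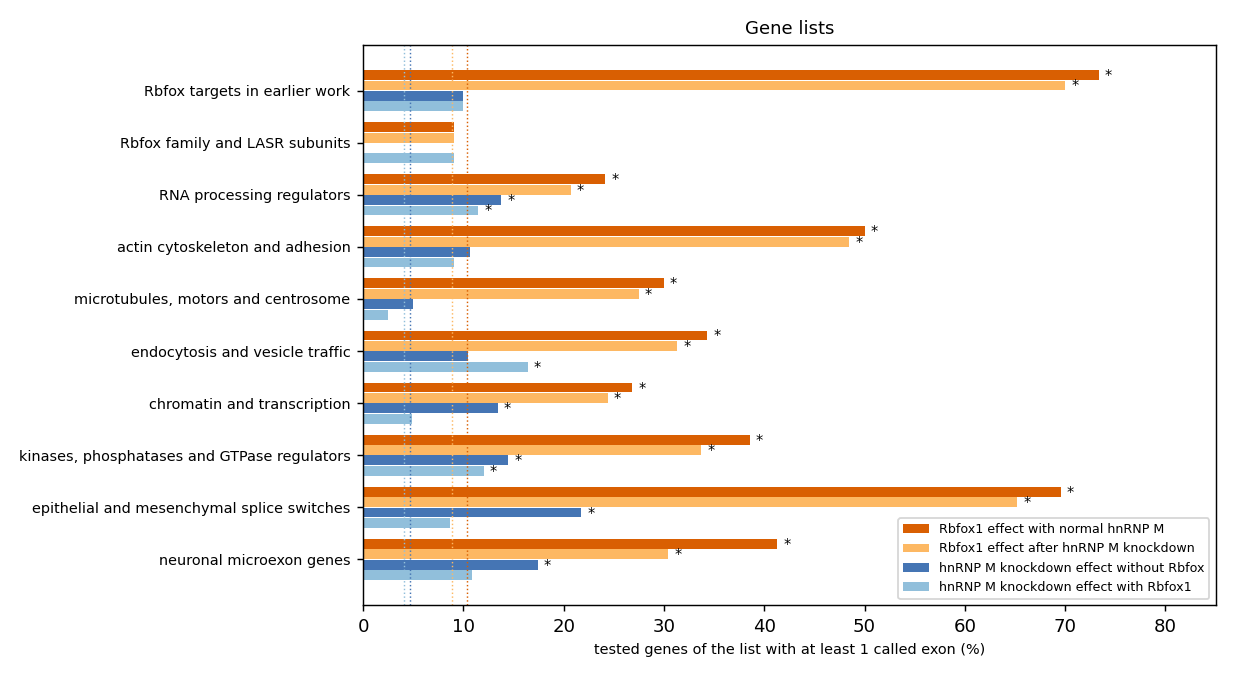
Share of the tested genes of each list with at least 1 called exon, in percent (horizontal axis), for the 4 comparisons (bars). Asterisks mark tests past the adjusted threshold and dotted lines the mean share among genes outside the list; Rbfox targets in earlier work reached 73.3% and 70% for Rbfox1 and 10.0% for either knockdown effect.

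The Rbfox family and the subunits of the large assembly of splicing regulators gave 1, 1, 0 and 1 called genes of 11, and the called gene was HNRNPC in each case (adjusted p 1, 1, 1 and 0.436). A 26-nt exon of its 5′ UTR (chromosome 14, 21731470 to 21731495) stood at 90.4% ± 0.404 in control cells, 80.2% ± 1.27 with Rbfox1, 86.1% ± 1.10 after knockdown and 73.5% ± 1.59 with both, and was called for Rbfox1 at both levels. Without library a or c of the control cells with Rbfox1 the difference with normal hnRNP M was -9.77 points, under the 10-point threshold, and the call also ended with PSI from raw counts and without the 2 libraries that stand apart. A neighbouring exon of 163 nt (21731826 to 21731988) stood at 11.6% ± 1.62, 18.7% ± 2.73, 12.7% ± 1.27 and 29% ± 4.57, and was called for Rbfox1 after knockdown (16.3 points) and for knockdown with Rbfox1 (10.2 points). The latter call ended without library b of the control or library b or c of the knockdown cells with Rbfox1, where the difference was 8.72 to 9.02 points. RBFOX2 had a 40-nt coding exon at 100%, 86.4% ± 9.09, 98% ± 3.41 and 76.4% ± 11.4, which did not pass the test (adjusted p 0.152 and 0.108 for Rbfox1). MATR3 (74.0% ± 5.65 in control cells, 64.8% ± 4.13 with Rbfox1, adjusted p 0.374), HNRNPH1 (86.8% ± 0.451 and 87.4% ± 1.36, 0.897) and HNRNPUL2 (90.7% ± 0.950 and 89.5% ± 1.31, 0.606) did not pass either.

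Exons called for Rbfox1 had lengths divisible by 3 more often than the others, 67.4% against 44.7% with normal hnRNP M (Fisher's exact p 8.58e-24, adjusted 1.03e-22) and 65.6% against 45.1% after knockdown (1.66e-17, adjusted 4.99e-17). With normal hnRNP M the share was 73.4% among exons that rose, such as those of FN1 and MARK3, and 59.3% among those that fell. The median length of the exons called for Rbfox1 was 96 nt against 115 nt (permutation p 0.0001, the smallest that 10000 permutations give). The others were all remaining tested exons, not matched on inclusion, depth or coding place. These results thus do not separate Rbfox1 exons from alternative exons in general. For knockdown the shares were 52.5% against 46.2% without Rbfox (Fisher's exact p 0.0759) and 48.2% against 46.4% with Rbfox1 (0.662). In the alternative settings the first result crossed the threshold in 7 of 26 (lowest p 0.000237) and the second in 1 of 26 (0.0458). Exons that fell on knockdown with Rbfox1 had a median length of 147 nt against 114 nt (permutation p 0.0003, adjusted 0.000720), and those that fell without Rbfox 115 nt against 114 nt (0.939).

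In the authors' deposited tables, 491, 411, 138 and 96 events passed their FDR with a difference of at least 10 points, for Rbfox1 with normal hnRNP M, Rbfox1 after knockdown, knockdown without Rbfox and knockdown with Rbfox1. Among the exons tested here their test gave 361, 313, 115 and 80 calls in the authors' deposited tables, of which 359, 311, 115 and 79 were also called here, all in the same direction, APLP2, PBRM1 and FN1 among them.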

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

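Both tests used here, the splits of the libraries and each exon's own dispersion, were chosen only after the result was seen. In simulated counts the test of the difference itself made 9 false calls among unchanged exons. The simulated set also held changed exons and gave more calls than the real data, so the 9 can not be set against the real count. In the real data the Rbfox1 effect differed between hnRNP M levels, by the same test, in 15 exons. The difference was 26.1 points in RHBDD2, 21.5 in ISCU, 18.5 in MLX, 15.5 in PPHLN1 and 14.2 in HMGA1, and -41.3 in HAPLN3, -28.6 in MPI, -25.5 in TRA2A, -22.6 in ZNFX1-AS1 and -13.5 in C1orf144.

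The splits of the libraries do not settle whether chance can be excluded: 11 of 100 gave as many exons as the real 15, the real split included, and the highest other split gave 920. All 10 others with as many leave the Rbfox1 labels whole at 1 hnRNP M level, which turns the Rbfox1 effect itself into a difference, a structure of the samples. The 9 false calls in the simulation came from a set with more calls and do not give the share of the 15 that is false. Chance as the source of some of the 15 stays open. A candidate explanation is that libraries vary more at these exons than the trend over all exons allows, and with each exon's own dispersion where larger, 2 of the 15 stayed called. That 2 stayed leaves open how far the excess variation goes, and dependence on hnRNP M, which the design names, stays open as well. Of the 10 named exons, those of HMGA1, ZNFX1-AS1 and C1orf144 were called in every leave-one-out fit, and of these only C1orf144 stayed called with its own dispersion where larger. HMGA1 was also lost with PSI from raw counts. No named exon was called with limma.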

How the results depend on the processing

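Tests chosen only after the data were seen were each exon's own dispersion and leaving out the 2 libraries that stand apart. Limma on empirical logits with pseudocount 0.5 called 338 exons for Rbfox1 with normal hnRNP M, 37 and 42 for knockdown without and with Rbfox1, 0 for the interaction, 187 for average knockdown and 40 for both averages. With 0.1 it called 281 and 287 for Rbfox1, 18 and 29 for knockdown, 0 for the interaction, 127 for average knockdown and 30 for both, and with 1 it called 84 and 69 for knockdown and 0 for the interaction. Without moderation the counts were 279, 225, 23, 18 and 0, with 385 and 81 for the averages and 22 for both. A threshold of 20 points gave 316, 290, 100, 94, 7, 317, 95 and 12, and of 5 points 920, 439 and 143 for the averages and both, as the thresholds imply. No filter gave 8 for the interaction, at least 50 mean reads 384 for average Rbfox1, own dispersion 2 for the interaction, and the authors' FDR 115 and 80 for knockdown, with 65 and 58 events at 20 points. Apart from the thresholds, the cause was not tested. Of 4970 values for named exons and lists, 4403 stayed on their side of the threshold, 550 lost it, 17 gained it and 0 reversed. This total includes settings that could hardly move a value, such as no dispersion floor, with 184 of 184 the same. Without moderation 73 of 184 lost the threshold, and with limma at 0.1 69 of 184. Gene totals, the host-gene test and the agreement of the knockdown effects were not run under the alternatives. The r of the Rbfox1 effects was 0.241 with no filter and 0.851 with PSI from raw counts. The share that rose moved from 57.4% to 68.7% (limma 0.1), 70.6% (no moderation) and 69.0% (20 points) for Rbfox1, from 60.3% to 70.7% (no moderation) after knockdown, from 64.6% to 78.4%, 83.3%, 78.3% and 77.0% (limma 0.5 and 0.1, no moderation, 20 points) for knockdown without Rbfox and from 61.0% to 73.8% (limma 0.5) with it. For average Rbfox1 it moved from 55.6% to 69.4% (20 points), for average knockdown from 61.0% to 71.6% (no moderation) and 74.7% (20 points). For the interaction it moved from 40% to 28.6% (20 points), 29.4% (raw counts) and 0 (own dispersion), to 27.3% without hnRNPMkd_noRbfox replicate a, and to 25% and 12.5% without hnRNPMkd_Rbfox1 replicate b and c. Leaving out each library in turn gave 435 to 530 and 395 to 459 exons for Rbfox1, 165 to 223 and 132 to 197 for knockdown, 8 to 17 for the interaction, 569 to 604 and 247 to 279 for the averages, 59 to 72 for both, an r of 0.717 to 0.751, 25 to 28 of the 40 list tests past the threshold, and HNRNPM at 5.46 to 8.66% and 5.45 to 6.47% of control. The edgeR and DESeq2 alternatives were not run, although the counts in the deposited cells can be split. The motif search (300 or 150 nt) was not run either, and it needs the genome. No paired analysis was possible because the values carry no replicate number, so the replicate block was not run. Changes of 15 points in the interaction were found in 20.9% of simulated cases.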

Other observations

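The tests by splits of the libraries and the permutations within classes from control cells were chosen only after the results were seen, and the other tests here were chosen once the patterns were known but fixed before their own values were seen. Read totals of genes, from the events in the tables, moved with both factors. SLC25A3, the mitochondrial phosphate carrier, stood at 153.7 ± 2.18 counts per megaread (CPM) in control cells and 23.8 ± 2.27 with Rbfox1 (SD, n = 3), a log2 change of -2.69 ± 0.13 (SE) with a limma adjusted p of 6.24e-09, and of -2.66 after knockdown. TKT, a transketolase, changed by -1.90 and -1.82, and CAT, the peroxisomal catalase, by -1.81 and -1.57. FKBP7 rose by 2.12 and 2.11, VAPB, a membrane contact protein, by 1.70 and 1.42, and SYP, the synaptic vesicle protein synaptophysin, by 1.56 and 1.53. In all, 962 of 5221 genes passed with normal hnRNP M and 895 after knockdown, with 48 and 38 at least doubled and 25 and 24 at most halved. The Rbfox1 cells were derived separately, so these totals can not be assigned to Rbfox1 rather than to the derivation. The totals hold inclusion and skipping reads at exons that were not called. A splicing change at neighbouring exons could move them without a change of expression, which was not tested.

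After knockdown, besides HNRNPM (-3.83 and -4.09 on the log2 scale without and with Rbfox1), EIF4G3, a translation initiation scaffold, changed by -3.30 ± 0.10 (SE) and -2.81, and OXCT1, an enzyme of ketone body use, by -2.54 and -2.79. CGA, the common subunit of glycoprotein hormones, rose by 2.54 and 2.25, TMEM59L by 2.48 and 1.67, ATP1B2, a sodium pump subunit, by 2.44 and 1.63, and the galectin gene LGALS1 by 2.38 and 1.62. EIF4G3 stood at 927 ± 42.3 CPM in control cells and 94.4 ± 7.10 after knockdown (limma adjusted p 1.33e-11, n = 3). In all, 1853 and 1472 genes passed. The hairpins differ from the control hairpin in sequence, and effects of the hairpins on other transcripts were not tested. The limit from splicing of neighbouring exons holds for these totals too.

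More exons were called for both average effects than independent lists would share, 69 against 24.2. A technical account is that deep exons of intermediate inclusion are easier to call for both. Permutations within classes of depth and mean inclusion gave up to 91, with a median of 70, but mean inclusion moves with the change itself. With classes of depth and inclusion in control cells the median was 58 and the highest 78, so this account can not be told apart from a true excess: 69 is above most permutations but not above the highest. Several exons of the same gene may add to it: with the deepest exon of each gene 39 were called for both. Permutations of these exons had a median of 36 and a highest of 51 with the first classes. With those from control cells the median was 32 and the highest 48. The 39 lies between median and highest in both cases, so with the deepest exon of each gene no excess over these permutations was shown. The directions were the same in 47 and opposite in 22 (Fisher's exact p 0.00326), which neither account was tested on. An exon near full skipping has little room to fall, and an exon near full inclusion little room to rise, under either effect. The Fisher test does not allow for this, nor for several exons of the same gene. Co-regulation by the 2 proteins stays open.

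Knockdown without Rbfox raised 144 of 223 called exons, 64.6% (exact 95% interval 57.9 to 70.8). A first explanation, that library c of the knockdown cells, which stands apart, alone made this excess, is excluded for that library: without it 65% rose (57.6 to 71.9). The intervals treat exons as independent and do not cover variation between cultures. The values argue against a second explanation, more room to rise than to fall: among called exons at 30 to 70% in control cells 72.7% rose (62.2 to 81.7). It is not excluded, because inclusion within that range was not matched and these exons share the same libraries. A repressive role of hnRNP M at more exons than not could be a biological reading, as a hypothesis found and tested on the same data. With Rbfox1 the share was 61.0% (53.8 to 67.9), and among exons at 30 to 70% it was 56.2% (44.1 to 67.8), an interval that includes 50.0.

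Called exons whose length is not a multiple of 3 might change the stability of the transcript. This would show as larger changes of the totals of their host genes, which were taken from exons that were not called. The median absolute log2 change did not differ detectably for Rbfox1 with normal hnRNP M (two-sided permutation p 0.844), and adjusted over the 4 comparisons p was 0.844, 0.844, 0.719 and 0.703, so the hypothesis stays open.

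For the average Rbfox1 effect 1 of 100 splits, the real one, gave as many as 603 called exons, and the highest other gave 255. For the average knockdown effect these were 282 and 108 (1 of 100). This argues against labels that carry no effect at all, and does not measure the share of false calls. For the pairwise effects, the 10 splits of 3 against 3 are too few for a share under 0.05. The real counts of 530, 459, 223 and 195 stood against at most 0, 0, 0 and 2 in the other splits. The other splits, those for the averages included, mostly mix both conditions within a group. This adds the effect to the dispersion, so their low counts do not measure false calls.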
